A study of Mus musculus with 12 samples.

How the data were processed

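Bone marrow cells of C57BL/6 mice were profiled by bulk RNA sequencing of stranded, poly(A)-selected libraries. The 12 libraries fell into 4 groups of 3. The groups named aged_WT and aged_KO came from Hopx wild-type and Hopx-knockout mice whose labels say old and give an age of 18 weeks. The groups named MN1_WT and MN1_KO came from the experiment with MN1 overexpression, with a labelled age of 16 weeks. Replicate numbers are those of the sample titles: 1, 6 and 7 for aged_WT, 3, 9 and 10 for aged_KO, 2, 3 and 4 for MN1_WT, and 5, 7 and 8 for MN1_KO. The labels give no sex and no sequencing batch. The aged and the MN1 libraries were deposited as separate tables, so labelled MN1 status, labelled age and table coincide.

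The deposited values used here are expected counts per gene symbol, which the authors' processing notes attribute to RSEM 1.2.28 with Bowtie2 2.3.4.3 on the mouse genome build mm10; the gene annotation was not stated. Each table holds 24444 gene symbols. Between 5.2 and 6.84% of the genes of a library had an expected count that was not whole, with no tolerance for rounding. The TPM and FPKM columns of the same tables were not used, because the counts behind them were available. No mitochondrially encoded genes and no immunoglobulin constant or variable region genes were found in the tables (0 of each), so neither class could be examined.

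Library totals ran from 16544407 to 28409046 counts. The 10 most abundant genes of a library took 4.9 to 14.5% of its total, and the largest single gene took 4.35%. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust dispersion) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each knockout effect was fitted on the 6 libraries of its own table. The difference of the knockout effects, MN1_WT against aged_WT, and MN1_KO against aged_KO were contrasts of 1 fit of all 12 libraries with 4 group means. Fold changes are on the log2 scale with their standard error (SE). Group values are means of TMM-scaled CPM (counts scaled to the library total) with their SD over 3 libraries, and values given for single libraries are CPM without TMM scaling. A group with 0 counts of a gene was given a floor of 3 counts over the group, and the fold is then written as a bound. Where a group held 1 to 3 counts, the ratio of counts is given with its exact 95% interval. These bounds and intervals cover counting error only.

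In all, 37 gene lists were written from textbook knowledge before the data were examined. They covered HSC stemness, quiescence regulators and cell-cycle inhibitors, mitosis, DNA replication, MYC and ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, the type I interferon response, antigen presentation and the interferon-gamma response, TNF and NF-kB inflammation, immediate early genes, heat shock, p53 targets, TGF-beta and BMP responses, the Wnt response, the Hoxa cluster with Meis1, and cholesterol and fatty acid synthesis. Cell type lists covered neutrophil primary granules, secondary granules and mature neutrophils, monocytes and macrophages, erythroid cells, megakaryocytes and platelets, eosinophils, basophils and mast cells, B cells, plasma cells, T and NK cells, dendritic cells, mesenchymal stroma, endothelium and adipocytes. The remaining lists held mitochondrially encoded genes, replication-dependent histones, sex-specific genes and the neighbours of Hopx on chromosome 5. How well poly(A) selection captured the histone transcripts was not tested, in any comparison. A list with fewer than 3 measured members in a comparison was not tested, which left out the mitochondrially encoded list everywhere and the sex-specific list in the aged comparison. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of 1 comparison, and again with an estimated correlation and with fry. Camera compares a list with the other genes; fry tests whether its genes move, on balance, 1 way. Members were counted at the threshold over all tested genes and adjusted over the list alone.

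Genes are named by a rule fixed before the data were examined: Hopx, Mn1, Cxcl12 and Cxcr4; up to 10 genes per direction with the largest change among those past the threshold, with a mean log2 CPM of at least 1, groups that do not overlap and a symbol that is not a predicted gene; up to 4 members with the smallest adjusted p of each list that passed or held 3 members past the threshold, and 2 of other lists; and, where fewer than 5 genes passed, the 5 with the smallest p per direction, given as not passing. A few genes that the rule names are not reported here, and counts of named genes whose effect differed leave them out and cover genes named in the aged or the MN1 comparison. The levels of further genes in single libraries were looked up after their values were seen. Positions are from GENCODE mouse release M21, in which 96.2% of the symbols were found.

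The alternatives were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, limma-trend with a prior count of 2, no filter, a stricter filter (CPM of 1 in 3 libraries and a mean CPM of 2), leaving out the 10 haemoglobin genes found, all 12 libraries in the fit, and leaving out each library in turn. One alternative, leaving out MN1_WT replicates 2 and 4, was added after the data were examined. The procedure was tested on simulated data with known changes. At a simulated 4-fold change, it recovered 99% of the genes in the aged comparison and 45% in the MN1 comparison; at a 2-fold change, it recovered 78% and 2.02%. Of all simulated calls, 20 of 223 in the aged comparison were false, more than the threshold of 0.05 allows on average, as were 3 of 50 in the MN1 comparison. In the aged comparison 2 lists that were not moved were also called. The simulated genes were drawn independently, whereas genes of the real lists were correlated (estimated at 0.452 for B cell genes in the aged comparison). The simulation therefore cannot show how often camera calls correlated lists falsely.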

Results

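Gene expression was measured by RNA sequencing in bone marrow cells of Hopx wild-type and Hopx-knockout mice, in 1 experiment labelled aged and in another in which MN1 was overexpressed. Hopx encodes a small homeodomain protein that does not bind DNA. MN1 is a transcriptional coregulator whose overexpression in marrow cells gives rise to acute myeloid leukaemia in mice. The 4 groups held 3 libraries each. The aged_WT libraries 1, 6 and 7 held 18579131, 21504947 and 19725874 counts. The aged_KO libraries 3, 9 and 10 held 18215490, 28409046 and 16544407 counts. The MN1_WT libraries 2, 3 and 4 held 25299033, 24084821 and 24977151 counts, and the MN1_KO libraries 5, 7 and 8 held 24312250, 20798116 and 22983872.

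Hopx (chromosome 5, 77086988 to 77115121, minus strand, mm10; overlapped by the antisense gene Hopxos on the plus strand) was nearly absent from the aged knockout. It stood at 14.2, 33.6 and 15.3 CPM in the aged_WT libraries, at 0 CPM in aged_KO replicates 3 and 9, and at 0.121 CPM in replicate 10. The aged_KO libraries held 2 Hopx counts in all against 1288 in aged_WT, a ratio of 680 after scaling (95% interval 188 to 5620; edgeR adjusted p = 0.000531). In the MN1 experiment Hopx was lower but present: 27.9, 14.1 and 25.6 CPM in MN1_WT replicates 2, 3 and 4, and 3.5, 3.51 and 2.92 CPM in MN1_KO replicates 5, 7 and 8. That difference, with a log2 fold change of -2.84 ± 0.38 (SE, n = 3 and 3), did not pass (edgeR adjusted p = 0.129).

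Mn1 (chromosome 5, 111417362 to 111457033, plus strand) did not follow the group labels. It stood at 47.3, 46.3 and 22.1 CPM in the MN1_KO libraries and at 36.4 CPM in MN1_WT replicate 3, but at 0.395 and 0.16 CPM in MN1_WT replicates 2 and 4, within the 0.0704 to 1.18 CPM of the aged libraries. Hoxa9 and Meis1, homeobox genes of haematopoietic progenitors, split the same way. Hoxa9 was at 143 CPM in MN1_WT replicate 3 against 9.41 and 2.08 CPM in replicates 2 and 4, and at 146, 93.8 and 29.6 CPM in the MN1_KO libraries. Meis1 was at 145 CPM in MN1_WT replicate 3 against 5.61 and 4.44 CPM, and at 122, 129 and 29.2 CPM in MN1_KO. The summed level of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y was at most 0.152 CPM in the aged libraries, all of which expressed Xist at 435 to 823 CPM. In the MN1 experiment the Y-linked sum was 241 and 229 CPM in MN1_WT replicates 2 and 4, 81.8 CPM in replicate 3, and 14.1, 21.6 and 8.05 CPM in MN1_KO, while Xist stood at 18.1, 2.4 and 4000 CPM in MN1_WT replicates 2, 4 and 3 and at 4940, 3920 and 585 CPM in MN1_KO.

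**Figure D1:**
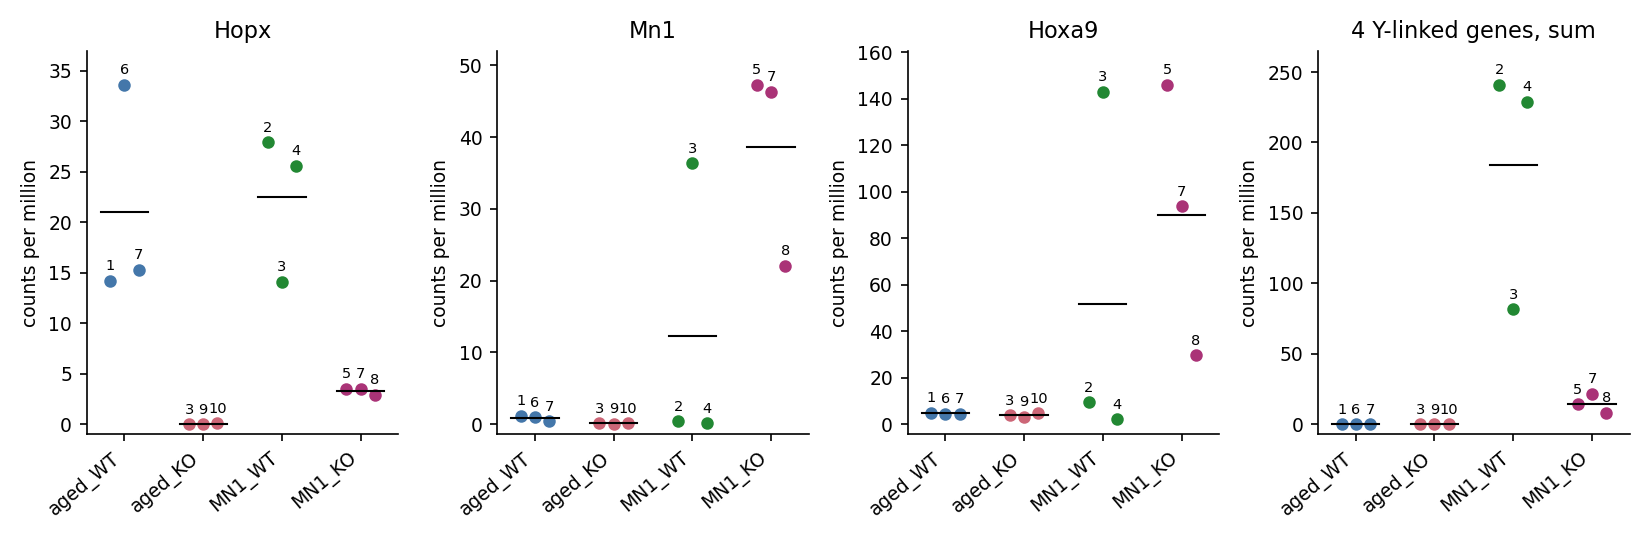
CPM of Hopx, Mn1, Hoxa9 and the sum of 4 Y-linked genes in each library (points, numbered by replicate), with the mean of each group of 3 as a line. MN1_WT replicates 2 and 4 lie at 0.395 and 0.16 CPM of Mn1, and MN1_WT replicate 3 at 36.4 CPM.

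Knockout against wild type in the aged experiment asks what loss of Hopx does to marrow expression. The B-lymphoid programme was lower in the aged_KO libraries by more than any other group of genes tested. Rag1, which with Rag2 cuts the antigen receptor loci, fell from 56.2 ± 7.1 CPM to 0.387 ± 0.53 CPM (SD, n = 3 and 3), and the B cell transcription factors Ebf1 and Pax5 fell from 24.8 ± 9.4 to 0.467 ± 0.3 CPM and from 13.8 ± 6.7 to 0.276 ± 0.23 CPM. T and NK cell, plasma cell, dendritic, eosinophil, erythroid and platelet genes were lower as well, whereas neutrophil granule genes, glycolysis genes and cholesterol synthesis genes were higher. These list calls, the B cell one included, rest on camera's preset correlation: with an estimated correlation 0 of 22 held (smallest adjusted p = 0.221). Nos2, the inducible nitric oxide synthase, rose from 0.237 ± 0.087 to 15.7 ± 11 CPM. Of 12771 genes tested with edgeR, 4008 changed: 1987 rose and 2021 fell.

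Large changes were mostly losses: of 416 genes that changed at least 4-fold, 39 rose and 377 fell. Besides Hopx and Rag1 (log2 fold change -6.91 ± 0.56, edgeR adjusted p = 0.000856), the deepest falls included Cpm, a carboxypeptidase, at -6.08 ± 0.37, Rag2 at -5.59 ± 0.61, and the surrogate light chain genes Vpreb3, Vpreb1 and Igll1 at -5.28, -5.26 and -5.20. Klhl14 was left with 2 counts in aged_KO against 244 in aged_WT (ratio 129, 95% interval 35.3 to 1070). The largest rises after Nos2 (6.01 ± 0.68, edgeR adjusted p = 0.00165) were those of Lipg, an endothelial lipase, at 3.99 ± 0.82, the glutathione-cleaving enzyme Ggt1 at 3.58 ± 0.29, and the acute-phase gene Saa3 at 3.52 ± 0.49. Others were Entpd3 at 3.51, Svep1 at 3.37, the neutrophil cytokine gene Prok2 at 3.30, Podxl at 3.04, the metalloreductase gene Steap4 at 2.85, and Igfbp6 at 2.77. Lipg did not pass without aged_WT replicate 1, aged_WT replicate 6 or aged_KO replicate 10 (edgeR adjusted p = 0.061, 0.063 and 0.06). Cxcl12, the chemokine that holds progenitors in the marrow, was at 20.5 ± 13 CPM in aged_KO and 57.9 ± 7.1 CPM in aged_WT and did not pass (edgeR adjusted p = 0.0847), although it did with DESeq2 (adjusted p = 0.048) and without aged_KO replicate 9 or 10 (edgeR adjusted p = 0.038 and 0.0093). Its receptor gene Cxcr4 was at 268 ± 52 against 344 ± 34 CPM (edgeR adjusted p = 0.0997, and 0.024 without aged_KO replicate 9).

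Among lymphoid lists, 22 of the 23 measured B cell genes fell and 1 did not pass, also 22 adjusted over the list alone and a median log2 fold change of -4.15 (camera adjusted p = 1.49e-36; adjusted p = 0.221 with an estimated correlation). Fcrla fell by 3.91 and the adaptor gene Blnk by 2.86 on the log2 scale. Of 21 T and NK cell genes, 19 fell, also 19 adjusted over the list alone (median -1.83, camera adjusted p = 6.79e-12; adjusted p = 0.378 with an estimated correlation). The T cell receptor component Cd3g was at -2.25 and Cd8b1 at -2.54. Of 11 plasma cell genes, 8 fell, also 8 adjusted over the list alone (median -1.92, camera adjusted p = 8.59e-09; adjusted p = 0.32 with an estimated correlation). The plasma cell regulator Irf4 fell by 2.78 and Sdc1 by 2.52. Of 11 Wnt response genes, 5 fell, 6 adjusted over the list alone (median -1.08, camera adjusted p = 0.00111; adjusted p = 0.221 with an estimated correlation). Its member Lef1, also a lymphocyte transcription factor, fell by 3.97, and Tcf7 stands in the T and NK cell list too.

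Myeloid, erythroid and platelet lists moved apart from the neutrophil lists. Of 16 dendritic cell genes, 12 fell, and adjusted over the list alone 12 fell and 1 rose (median -1.50, camera adjusted p = 1.72e-10; adjusted p = 0.305 with an estimated correlation). Its members Ly6d and Klk1 fell by 3.62 and 2.84, but whether their transcripts came from dendritic cells was not tested. Of 18 megakaryocyte and platelet genes, 16 fell and 1 rose, 16 and 2 adjusted over the list alone (median -1.66, camera adjusted p = 7.06e-10; adjusted p = 0.438 with an estimated correlation). The glycoprotein genes Gp5 and Gp9 fell by 2.25 and 2.08, and the platelet tubulin Tubb1 by 2.28. Of 23 erythroid genes, 15 fell and 1 rose, 20 and 1 adjusted over the list alone (median -1.51, camera adjusted p = 1.2e-06; adjusted p = 0.544 with an estimated correlation). The erythroid transcription factors Gata1 and Klf1 fell by 1.43 and 1.51. Of 10 eosinophil genes, 7 fell, also 7 adjusted over the list alone (median -1.54, camera adjusted p = 0.000808; adjusted p = 0.544 with an estimated correlation). Eosinophil peroxidase, Epx, fell from 300 ± 42 to 107 ± 40 CPM. The monocyte and macrophage list fell with 8 of 21 members, 9 adjusted over the list alone (median -0.18, camera adjusted p = 0.000808; adjusted p = 0.544 with an estimated correlation). The members that fell included the macrophage genes Cd5l at -2.48 and Mrc1 at -2.28. Of 10 basophil and mast cell genes, 4 fell and 1 rose, 6 and 1 adjusted over the list alone (median -1.25, camera adjusted p = 0.0175; adjusted p = 0.571 with an estimated correlation). This list no longer passed without aged_WT replicate 1 or aged_KO replicate 10 (camera adjusted p = 0.068 and 0.11).

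Neutrophil genes were higher in the aged knockout. Of 16 secondary granule genes, 11 rose, 13 adjusted over the list alone (median 0.75, camera adjusted p = 1.15e-07; adjusted p = 0.438 with an estimated correlation). Cd177 rose from 1427 ± 147 to 3060 ± 256 CPM and lipocalin 2, Lcn2, from 3707 ± 413 to 6645 ± 585 CPM. Of 20 mature neutrophil genes, 9 rose, 10 adjusted over the list alone (median 0.57, camera adjusted p = 4.26e-05; adjusted p = 0.544 with an estimated correlation). The gelatinase gene Mmp9 rose by 0.95 and the activating receptor gene Trem1 by 1.18. Of 15 primary granule and granulocyte progenitor genes, 9 rose, also 9 adjusted over the list alone (median 0.59, camera adjusted p = 0.00198; adjusted p = 0.557 with an estimated correlation). Ficolin B, Fcnb, rose by 0.59.

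Glycolysis and hypoxia genes rose with 16 of 24 members, 18 adjusted over the list alone (median 0.64, camera adjusted p = 7.06e-10; adjusted p = 0.221 with an estimated correlation). The glucose transporter Slc2a1 rose from 27.3 ± 1.8 to 70.7 ± 6.2 CPM and the lactate transporter Slc16a3 from 136 ± 6.4 to 278 ± 29 CPM. Cholesterol and fatty acid synthesis genes rose with 14 of 23 members while 1 fell, 15 and 1 adjusted over the list alone (median 0.45, camera adjusted p = 4.26e-05; adjusted p = 0.485 with an estimated correlation). Hmgcs1, of an early enzyme of sterol synthesis, rose by 0.68. Mitotic genes rose with 11 of 26 members, 13 adjusted over the list alone (median 0.28, camera adjusted p = 0.00182; adjusted p = 0.544 with an estimated correlation). The mitotic kinase Plk1 rose by 0.43. Cytosolic ribosomal protein genes fell with 22 of 43 members, 32 adjusted over the list alone (median -0.51, camera adjusted p = 6.66e-07; adjusted p = 0.557 with an estimated correlation). Rps7 fell by 0.73.

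Antigen presentation and interferon-gamma response genes fell with 22 of 28 members, 25 adjusted over the list alone (median -1.05, camera adjusted p = 1.67e-11; adjusted p = 0.221 with an estimated correlation). The class I gene H2-K1 fell from 1148 ± 121 to 563 ± 6.91 CPM. Type I interferon response genes fell with 8 of 26 members, 9 adjusted over the list alone (median -0.75, camera adjusted p = 0.000534; adjusted p = 0.571 with an estimated correlation). Bst2, which tethers viruses, fell by 1.51. Of 30 HSC stemness genes, 16 fell and 2 rose, also 16 and 2 adjusted over the list alone (median -0.75, camera adjusted p = 0.000185; adjusted p = 0.221 with an estimated correlation). The stem cell surface gene Slamf1 fell by 2.48 and the transcription factor gene Gata2 by 1.19, while Erg rose by 0.87. Endothelial genes fell with 8 of 19 members while 1 rose, 10 and 1 adjusted over the list alone (median -0.86, camera adjusted p = 0.00258; adjusted p = 0.43 with an estimated correlation). Cd34, also a progenitor gene, fell by 0.71. Mesenchymal stroma and osteolineage genes fell with 4 of 18 members, also 4 adjusted over the list alone (median -0.54, camera adjusted p = 0.0263; adjusted p = 0.485 with an estimated correlation). Alkaline phosphatase, Alpl, fell by 2.44. Without aged_WT replicate 1 this list did not pass (camera adjusted p = 0.069).

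**Figure D2:**
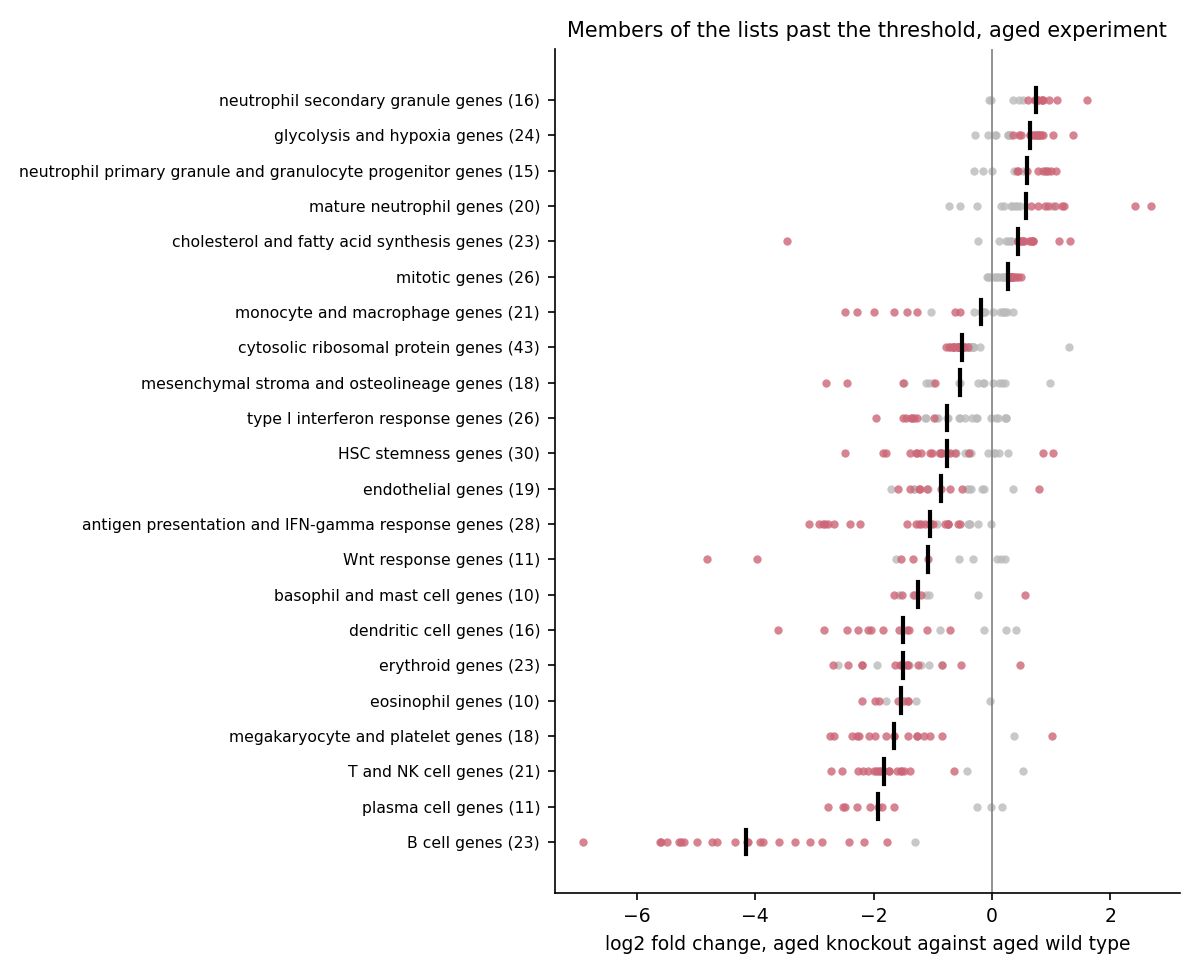
Log2 fold change of aged_KO against aged_WT for each measured member of the 22 lists past the threshold (points; red where the edgeR adjusted p was under 0.05, grey otherwise), with the median of each list as a black line and the number of members in brackets. The B cell list has a median of -4.15, and the secondary granule list a median of 0.75.

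The other 13 lists did not pass in the aged comparison. Quiescence regulators and cell-cycle inhibitors had 4 of 19 members higher and 1 lower (camera adjusted p = 0.292), with Foxo1 at -1.93, and p53 targets 2 of 19 higher and 1 lower (0.808). TGF-beta and BMP response genes had 5 of 18 higher and 3 lower (0.782), with Id3 at -2.54, and TNF and NF-kB genes 3 of 25 higher and 3 lower (0.755), with Bcl3 at 1.27 and Cd40 at -2.26. Adjusted over the list alone, these counts were 4 and 1, 2 and 1, 5 and 4, and 2 and 3. Immediate early genes had 1 of 20 higher and 2 lower (0.782), heat shock genes 2 of 14 lower (0.409), and the neighbours of Hopx 3 of 13 higher and 2 lower (0.332); adjusted over the list alone the counts were 1 and 2, 2, and 5 and 2. Of 7 adipocyte genes, 2 were higher and 4 lower (camera adjusted p = 0.292), as many adjusted over the list alone, with Adipoq at -2.81. Oxidative phosphorylation (2 of 37 lower, camera adjusted p = 0.0557), DNA replication (2 of 26 lower, 0.292) and MYC and ribosome biogenesis genes (1 of 22 higher and 1 lower, 0.653) had 0 members past the threshold adjusted over the list alone. The Hoxa cluster with Meis1 (6 measured) and the histone list (20) had 0 members past either edgeR threshold (camera adjusted p = 0.39 and 0.782). By fry the Hoxa list passed downward (fry adjusted p = 0.011). In the TNF, p53 and TGF-beta lists the mean lay below 0 while the median and the test pointed up, and in the immediate early list both lay below 0 while the test pointed up. Oxidative phosphorylation passed, downward, with the stricter filter, limma-trend or without aged_KO replicate 10 (camera adjusted p = 0.022, 0.0072 and 0.00029), immediate early genes passed, upward, without aged_WT replicate 7 (0.049), and adipocyte genes passed, downward, without aged_KO replicate 3 (0.026).

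In 6180 genes (48.4%) the aged groups did not overlap, where chance gives 10%. The count of 4008 fell to 2560 without aged_WT replicate 6, to 2402 without aged_WT replicate 7, and to 818 when all 12 libraries set the spread. With an estimated correlation 0 of the 22 list calls held, and with fry 15 lists passed, among them the Hoxa list, which is not among the 22.

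By the labels, knockout against wild type within the MN1 experiment asks whether loss of Hopx alters marrow that overexpresses MN1. As lists, sex-specific, B cell, T cell and eosinophil genes were among those lower in MN1_KO, but no single gene passed, and with an estimated correlation 0 of 22 list calls held (smallest adjusted p = 0.409). MN1_WT was itself mixed: replicate 3 had Mn1 at 36.4 CPM, and replicates 2 and 4 at 0.395 and 0.16 CPM. The Y-linked sum was 81.8 to 241 CPM in MN1_WT and 8.05 to 21.6 CPM in MN1_KO. Loss of Hopx therefore cannot be told apart here from Y-linked level, nor fully from Mn1 level. Of 13525 genes tested with edgeR, 0 changed. At an unadjusted p under 0.05 there were 1353, of which 568 were higher and 785 lower in MN1_KO; DESeq2 called 565 and limma-trend 6. The groups did not overlap in 2068 genes (15.3%, where chance gives 10%).

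The genes with the smallest p did not pass and are given as values (n = 3 and 3). The noradrenaline transporter gene Slc6a2 was at 28.9 ± 17 CPM in MN1_KO and 0.0655 ± 0.039 CPM in MN1_WT, the matrix gene Thbs4 at 17 ± 9.9 against 0.361 ± 0.092, the endocytic receptor gene Lrp1 at 2446 ± 970 against 187 ± 49.3, and Nrg4 at 34.6 ± 9.1 against 3.47 ± 1.2 CPM. The kinase gene Rps6ka2 was at 403 ± 94 against 67.1 ± 13 CPM (edgeR adjusted p = 0.0986 for each of these 5). Lower in MN1_KO were Gm18853, Skint3 (0.213 ± 0.038 against 5.46 ± 2.6 CPM), the scavenger receptor gene Marco (0.213 ± 0.038 against 3.98 ± 1.5 CPM) and Ggt1 (1.52 ± 0.25 against 10.8 ± 4 CPM). Gm18853, a pseudogene that lies within Gvin1, had 0 counts in MN1_KO and in the aged libraries and 23.6 ± 8.8 CPM in MN1_WT, at least 544-fold lower in MN1_KO, and reads of related Gvin sequences were not told apart here. Mn1 was at 37.3 ± 11 CPM in MN1_KO and 11 ± 19 CPM in MN1_WT (edgeR adjusted p = 0.796), Cxcl12 at 36.7 ± 17 and 92.9 ± 50 CPM (0.408), and Cxcr4 at 176 ± 58 and 239 ± 81 CPM (0.759). The stefin genes Stfa2 and BC100530 were at 1048 ± 1079 and 3213 ± 2903 CPM in MN1_KO against 4.43 ± 2.1 and 10.2 ± 9.1 CPM in MN1_WT (edgeR adjusted p = 0.129 for both); they are near-identical paralogs, so the level of each is uncertain.

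By camera 22 of 36 lists passed, 3 upward and 19 downward, while with an estimated correlation and with fry 0 passed. B cell genes fell as a list, with a median of -3.22 over 22 genes of which 0 passed over all genes and 18 were lower adjusted over the list alone (camera adjusted p = 1.52e-17; adjusted p = 0.444 with an estimated correlation). Rag1 was at 2.25 ± 1.3 against 41.8 ± 36 CPM, and MN1_WT replicate 3, at 4.53 CPM, lay near the knockout libraries. Eosinophil genes fell as a list (median -1.98, 0 of 10 passing, 3 lower adjusted over the list alone, camera adjusted p = 3.65e-09; adjusted p = 0.444 with an estimated correlation). So did T and NK cell genes (median -1.18, 0 of 21, 12 adjusted over the list alone, 3.65e-09; adjusted p = 0.533 with an estimated correlation), and monocyte and macrophage genes (median -0.66, 0 of 21, 4 adjusted over the list alone, 5.55e-07; adjusted p = 0.533 with an estimated correlation). Mitotic genes (median -0.58, 0 of 26, 0 adjusted over the list alone, camera adjusted p = 1.4e-07; adjusted p = 0.533 with an estimated correlation) were lower. Cholesterol synthesis genes were lower too (median -0.50, 0 of 23, 7 adjusted over the list alone, camera adjusted p = 5.55e-07; adjusted p = 0.444 with an estimated correlation), with Idi1 at 22.6 ± 2.6 against 47.7 ± 13 CPM. The upward lists were cytosolic ribosomal proteins (median 0.42, 0 of 43, 0 adjusted over the list alone, camera adjusted p = 7.64e-09; adjusted p = 0.533 with an estimated correlation), the Hoxa cluster with Meis1 (median 0.93, 0 of 11, 0 adjusted over the list alone, 0.00245; adjusted p = 0.596 with an estimated correlation) and type I interferon response genes (median 0.32, 0 of 26, 0 adjusted over the list alone, 0.017; adjusted p = 0.626 with an estimated correlation). The sex-specific list, with median -3.74 over 5 genes, fell too (0 of 5 passing, 4 lower adjusted over the list alone, camera adjusted p = 2.89e-09; adjusted p = 0.409 with an estimated correlation). Mature neutrophil genes did not pass, with a median of -0.41 and a mean of 0.47 while the test pointed down (camera adjusted p = 0.351). Without MN1_KO replicate 5 that list passed upward (camera adjusted p = 0.048).

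MN1_WT replicate 3 weighed most on this comparison: 896 genes passed without it (455 higher and 441 lower). The count was 3 without MN1_KO replicate 5 and 0 without any 1 of the other 4 libraries. Replicate 3 is the only MN1_WT library with high Mn1 (36.4 CPM), so without it low Mn1 and wild type coincide. The 896 genes therefore cannot be read as effects of Hopx alone. Without MN1_WT replicates 2 and 4, whose Mn1 was low, 0 genes and 13 lists passed, and the mitotic list turned to a median of 0.10 without passing, while the Hoxa list passed downward (median -0.33, camera adjusted p = 0.018).

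The difference of the 2 knockout effects was tested directly. Relative to the aged experiment, the knockout effect in the MN1 experiment was more positive for Hopx itself and for platelet, ribosomal protein and interferon genes, and more negative for neutrophil granule, cholesterol synthesis and mitotic genes. For the lists this rests on camera's preset correlation: with an estimated correlation 0 of 16 differed (smallest adjusted p = 0.693). Ggt1 had a log2 fold change of 3.58 in the aged and -2.83 in the MN1 experiment, Lipg of 3.99 and -3.32, and Nos2 of 6.01 and -0.52. Of 13937 genes tested with edgeR, the effect differed in 463, with 196 positive and 267 negative differences. In the MN1 experiment knockout and Y-linked level coincide, and Mn1 was low in MN1_WT replicates 2 and 4. These differences therefore cannot be ascribed to loss of Hopx alone.

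The largest named differences were those of Lipg at -7.31 ± 1.05 (SE), Nos2 at -6.56 ± 0.85, Lmo7 at 6.53 ± 0.55, Rag2 at 6.46 ± 1.19, Ggt1 at -6.43 ± 0.51 and Hopx at 6.12 ± 0.96 (edgeR adjusted p = 0.0114, 0.00655, 0.000906, 0.0222, 0.000906 and 0.0133). Those of Mn1, Cxcl12 and Cxcr4 were 4.25 ± 2.25, 0.15 ± 0.72 and -0.09 ± 0.39 and did not pass (edgeR adjusted p = 0.288, 0.927 and 0.919). By camera 16 of 36 lists differed, 8 in each direction. Members counted below as positive or negative are only those past the threshold, over all genes or over the list alone. Cytosolic ribosomal protein genes had a median difference of 0.92, with 4 of 43 positive and 39 adjusted over the list alone (camera adjusted p = 8.46e-18; adjusted p = 0.693 with an estimated correlation). Megakaryocyte and platelet genes had a median of 1.33, with 3 of 18 positive and, adjusted over the list alone, 8 positive and 1 negative (9.2e-05; adjusted p = 0.693 with an estimated correlation). Gp5 differed by 3.26. Cholesterol and fatty acid synthesis genes had a median of -0.95, with 9 of 23 negative and, adjusted over the list alone, 15 negative and 2 positive (camera adjusted p = 1.56e-10; adjusted p = 0.693 with an estimated correlation). Mitotic genes had a median of -0.85, with 2 of 26 negative and 11 adjusted over the list alone (5.44e-09; adjusted p = 0.725 with an estimated correlation). Secondary granule genes had a median of -1.18, with 2 of 16 negative, also 2 adjusted over the list alone (1.5e-05; adjusted p = 0.725 with an estimated correlation). The neutrophil surface gene Ly6g differed by -3.82, but its reads are shared in part with related Ly6 genes.

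**Figure D3:**
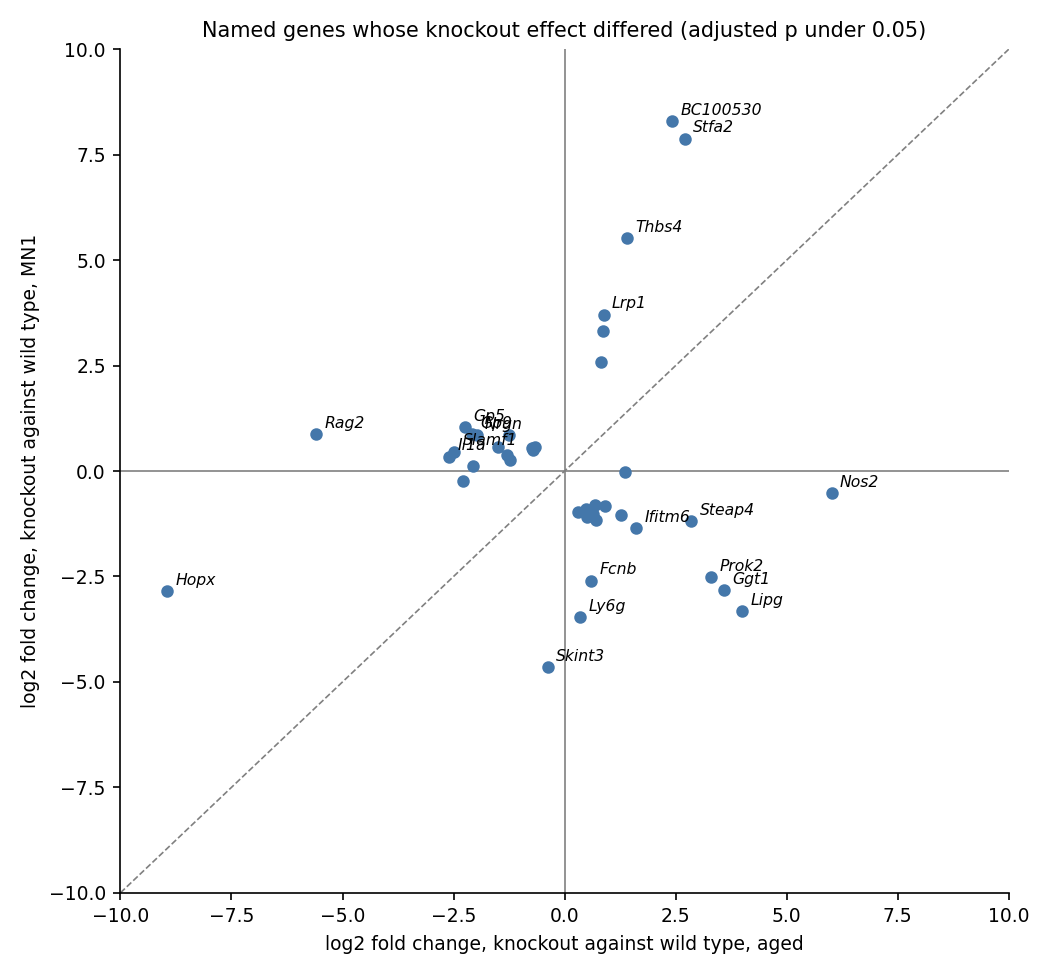
Log2 fold change of knockout against wild type in the aged experiment (horizontal) and in the MN1 experiment (vertical) for the 40 genes named in either experiment's own comparison whose effect differed between them; the dashed line marks equal effects. For 31 of the 40 genes the signs are opposite, as for Ggt1 at 3.58 and -2.83.

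With MN1_WT replicate 3 left out, low Mn1 and the MN1 wild-type group coincide. Each library weighed on the count of 463. It was 132, 67 and 53 without aged_WT replicates 1, 6 and 7, 84, 63 and 257 without aged_KO replicates 3, 9 and 10, 81, 3337 and 97 without MN1_WT replicates 2, 3 and 4, and 296, 218 and 857 without MN1_KO replicates 5, 7 and 8; without MN1_WT replicates 2 and 4 together it was 40, and with DESeq2 1671.

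Overlap between the knockout effects could not be counted at the threshold, since 0 genes passed in the MN1 experiment against 3882 of the 12471 genes tested in both that changed in the aged one. At an unadjusted p under 0.05 in both, 330 genes were lower in both knockouts where 160 would be shared if the effects were independent (Fisher's exact test, 2-sided, odds ratio 3.19, p = 3.6e-47). For genes higher in both the count was 102 against 89.2 (Fisher's exact test, odds ratio 1.2, p = 0.13). Another 314 genes went opposite ways, against 248. Genes are not independent replicates, so these p describe genes and not animals. Across the 12471 genes the log2 fold changes correlated with Pearson's r = 0.146 and Spearman's rho = -0.141, and 40.3% of the 3882 genes changed in the aged experiment had the same sign in the MN1 experiment.

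Wild type was next compared between the experiments. Immediate early and heat shock genes were lower in MN1_WT than in aged_WT, as were platelet, plasma cell, dendritic cell and ribosomal protein genes. Of these list calls 0 held with an estimated correlation. The monocyte and macrophage list was lower too (median -0.53, 0 of 21 passing, 0 adjusted over the list alone, camera adjusted p = 0.0263; adjusted p = 0.692 with an estimated correlation), although 2 genes of activated macrophages outside it were higher. The stress genes Fosb and Jun fell from 91.9 ± 57 to 1.97 ± 1.4 CPM and from 377 ± 240 to 43.7 ± 14 CPM (SD, n = 3 and 3), and these 2, Gpnmb and Mmp12, rose from 2.62 ± 0.73 to 104 ± 65 CPM and from 0.104 ± 0.13 to 53.1 ± 38 CPM. Of 13937 genes tested with edgeR, 499 changed: 140 rose and 359 fell. Labelled age, Y-linked expression and table coincide in this comparison and cannot be told apart. The levels of Mn1 and of Xist do not coincide with them, and some shifts were present where it was low: in MN1_WT replicates 2, 3 and 4, Hspa1a stood at 1.15, 0.374 and 1 CPM and Gpnmb at 91, 56.5 and 177 CPM.

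Albumin, Alb, a liver gene, was at 19.8 to 38.3 CPM in the 6 aged libraries and at 0 CPM in the 6 MN1 libraries, at least 594-fold lower in MN1_WT (edgeR adjusted p = 0.000945). The Y-linked genes were higher in MN1_WT: Ddx3y, Eif2s3y and Kdm5d had 2 counts each in aged_WT, with ratios of 2100 (95% interval 582 to 17400), 2150 (594 to 17700) and 764 (211 to 6310), and Uty had 0 counts there and was at least 330-fold higher. The heat shock genes Hspa1a and Hspa1b, near-identical in sequence, fell by 5.91 and 4.96 on the log2 scale, the dendritic cell genes Cd209a and Klk1 by 4.59 and 4.65, and Hepacam2 by 4.50. Hopx was at 21.4 ± 8.3 CPM in MN1_WT and 21.8 ± 12 CPM in aged_WT, and Mn1, Cxcl12 and Cxcr4 did not pass either (edgeR adjusted p = 0.974, 0.167, 0.627 and 0.124).

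By camera 20 of 36 lists passed, 6 upward and 14 downward, 10 passed with fry, and with an estimated correlation the sex-specific list alone held (adjusted p = 0.00804 with an estimated correlation). Immediate early genes fell with 7 of 20 members, 13 adjusted over the list alone (median -1.71, camera adjusted p = 9.99e-13; adjusted p = 0.226 with an estimated correlation). Heat shock genes fell with 7 of 14, 8 adjusted over the list alone (median -0.81, 1.23e-07; adjusted p = 0.206 with an estimated correlation). Cytosolic ribosomal protein genes fell with 15 of 43 members, 36 adjusted over the list alone (median -0.70, camera adjusted p = 6.18e-22; adjusted p = 0.271 with an estimated correlation). Megakaryocyte and platelet genes fell with 8 of 18, 11 adjusted over the list alone (median -1.59, camera adjusted p = 4.95e-12; adjusted p = 0.103 with an estimated correlation). The platelet glycoprotein gene Gp1bb fell by 1.75. Plasma cell genes fell with 6 of 11, 9 adjusted over the list alone (median -1.92, camera adjusted p = 7.26e-11; adjusted p = 0.0914 with an estimated correlation). Derl3 fell by 3.20. MYC and ribosome biogenesis genes rose with 1 of 22, 8 adjusted over the list alone (median 0.41, camera adjusted p = 1.14e-05; adjusted p = 0.467 with an estimated correlation). For HSC stemness genes the median was 0.28 while the test pointed down, without passing (camera adjusted p = 0.643).

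The count of 499 was 135, 78 and 103 without aged_WT replicates 1, 6 and 7 and 130 without MN1_WT replicate 2, 329 with the stricter filter and 1791 with DESeq2. Without MN1_WT replicates 2 and 4 together it was 2465, with 1691 genes higher, and the HSC stemness list passed upward with a median of 1.15.

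In the knockouts, the MN1 experiment differed from the aged one in Hoxa and interferon genes, which were higher in MN1_KO, and in immediate early, neutrophil, cholesterol synthesis and mitotic genes, which were lower. With an estimated correlation 0 of these list calls held (smallest adjusted p = 0.404). Single genes of the basophil and mast cell list were higher, while the list did not pass (5 of 12 higher, also 5 adjusted over the list alone, camera adjusted p = 0.0604). Gata2, a transcription factor of stem and mast cells, rose from 17.2 ± 3.5 to 483 ± 140 CPM, and the mast cell protease Cpa3 from 37.3 ± 17 to 1596 ± 1245 CPM (SD, n = 3 and 3). Both were also high in MN1_WT replicate 3, where Mn1 was high. Gata2 stood there at 793 CPM against 81.9 and 68.6 CPM in MN1_WT replicates 2 and 4, and Cpa3 at 2040 against 352 and 161 CPM. Interleukin 1 beta, Il1b, fell from 161 ± 77 to 12.2 ± 7 CPM, and the proliferation gene Mki67 from 1453 ± 55.2 to 550 ± 41.7 CPM. Of 13937 genes tested with edgeR, 5281 changed: 2936 rose and 2345 fell. Here MN1 status, labelled age, the low level of Y-linked expression and table cannot be told apart.

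Several genes with few or 0 counts in aged_KO were abundant in MN1_KO. The glutamate receptor gene Gria2 was at least 3805-fold higher, the keratin Krt9 at least 1716-fold, P-cadherin, Cdh3, at least 1164-fold, and the germ cell gene Dazl at least 1058-fold; Esyt3 had 1 count in aged_KO (ratio 9560, 95% interval 1710 to 377000). Gria2, Dazl and Krt9 were also at 737, 131 and 16.7 CPM in MN1_WT replicate 3, against 2.81 CPM or less in replicates 2 and 4. Gria2 did not pass without aged_KO replicate 9, nor Dazl and Krt9 without any 1 aged_KO replicate. Mn1 was at 33.9 ± 10 against 0.159 ± 0.066 CPM (edgeR adjusted p = 0.0102, though it did not pass with DESeq2), and Hopx had 225 counts in MN1_KO against 2 in aged_KO (ratio 104, 95% interval 28.6 to 867). Cxcr4 fell by 0.88 (edgeR adjusted p = 0.0308), a call that held only without MN1_KO replicate 8 when 1 library was left out, and Cxcl12 did not pass (0.392). Alb was at least 841-fold lower in MN1_KO.

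By camera 24 of 36 lists passed, 8 upward and 16 downward, 25 passed with fry and 0 with an estimated correlation. Immediate early genes fell with 16 of 20 members, also 16 adjusted over the list alone (median -2.40, camera adjusted p = 2.5e-09; adjusted p = 0.404 with an estimated correlation). Fos fell by 5.01 and Fosb by 5.60. Mitotic genes fell with 17 of 26, 24 adjusted over the list alone (median -0.87, camera adjusted p = 2.66e-08; adjusted p = 0.404 with an estimated correlation). Secondary granule genes fell with 10 of 16, also 10 adjusted over the list alone (median -1.39, camera adjusted p = 1.06e-06; adjusted p = 0.404 with an estimated correlation). Ly6g fell by 4.50. Histone genes fell with 15 of 20, 17 adjusted over the list alone (median -2.05, camera adjusted p = 6.24e-07, and 0.404 with an estimated correlation). The libraries were poly(A)-selected, and a difference in the capture of histone transcripts between the experiments was not tested. Type I interferon response genes rose with 17 of 26 members, and adjusted over the list alone 21 rose and 1 fell (median 1.26, camera adjusted p = 6.24e-07; adjusted p = 0.404 with an estimated correlation). Irf7, a regulator of interferon genes, rose by 1.97. The Hoxa cluster with Meis1 rose with 9 of 11 members, 10 adjusted over the list alone (median 4.08, camera adjusted p = 0.00118; adjusted p = 0.473 with an estimated correlation). Hoxa10 rose by 6.49 ± 1.76.

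The count of 5281 was 3083 and 2515 without aged_KO replicates 3 and 9, and 3369 and 3234 without MN1_KO replicates 5 and 7. Hoxa9 and Meis1 did not pass without any 1 aged_KO replicate.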

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

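The tests of explanations for Mn1, for the B cell genes and for Hopx below were chosen after the results were seen; the counts of other splits of the samples were planned. Everything in the first 3 paragraphs is here because a test of the difference between the knockout effect in the MN1 experiment and that in the aged experiment passed its threshold. The effect differed in 463 genes. Of 100 splits of the samples, the real grouping included, 10 gave as many, so chance cannot be excluded for this count. Apart from the real grouping, each of these put MN1_WT replicates 2 and 4 with MN1_KO replicate 8 against the other MN1 libraries. The share thus reflects 1 structure of the MN1 libraries, and it cannot decide about chance. The highest other split put MN1_WT replicates 2 and 4 with MN1_KO replicate 8 and kept the aged groups as labelled. It gave 4492 genes, a count that thus includes the aged knockout effect. With the sides of that MN1 split exchanged and the aged groups as labelled, the count was 2812. The same MN1 split, either way round, with the aged libraries mixed gave 435 to 1565 genes. These counts point to a structure of the MN1 samples other than their group.

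Among lists, the median difference was positive for HSC stemness (0.94), ribosomal protein (0.92), type I interferon (0.99), antigen presentation (0.71), Hoxa and Meis1 (1.67), megakaryocyte and platelet (1.33), B cell (0.92) and T and NK cell genes (0.59). It was negative for mitotic (-0.85), glycolysis and hypoxia (-0.55), TNF and NF-kB (-0.55), cholesterol synthesis (-0.95), primary granule (-1.26), secondary granule (-1.18), mature neutrophil (-0.89) and histone genes (-0.83). In the mature neutrophil list the members past the threshold mostly went the other way: 3 were positive, stefin genes such as Stfa2 and BC100530, and 1 was negative (3 and 5 adjusted over the list alone; mean -0.23). Without MN1_WT replicates 2 and 4, camera's direction turned for HSC stemness (median 0.038) and for Hoxa and Meis1 genes (0.31), and neither list passed. With an estimated correlation 0 of these 16 passed camera, and 4 lists passed fry.

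Of the genes named in the aged or in the MN1 comparison, 40 differed by edgeR; others, such as Lmo7 (6.53), were named for the difference alone. Many such calls are not stable: over the 124 genes named for this contrast, 41 were lost without MN1_WT replicates 2 and 4 and 308 over the runs with 1 library left out. The 22 positive differences were those of BC100530 (5.85), Bst2 (2.06), Eaf2 (2.16), Gp5 (3.26), Gp9 (2.92), H2-DMa (1.49), H2-DMb1 (1.67), Hopx (6.12), Il1a (2.95), Lrp1 (2.82), Mrc1 (2.04), Nrg4 (2.42), Nrgn (2.79), Rag2 (6.46), Rpl35 (1.2), Rps24 (1.22), Rps6ka2 (1.76), Rps7 (1.26), Slamf1 (2.92), Stfa2 (5.16), Thbs4 (4.11) and Xaf1 (2.11). The negative ones were those of Bcl3 (-2.32), Clec4e (-1.74), Fcnb (-3.19), Ggt1 (-6.43), Hmgcs1 (-1.49), Idi1 (-1.58), Ifitm6 (-2.97), Lipg (-7.31), Ly6g (-3.82), Mki67 (-1.41), Msmo1 (-1.86), Nos2 (-6.56), Prok2 (-5.84), Skint3 (-4.22), Slc2a1 (-1.41), Sqle (-1.67), Steap4 (-4.03) and Top2a (-1.28). Reads of the stefin, ribosomal protein and Ly6 genes are shared with paralogs, so their single values are uncertain.

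Mn1 was low in MN1_WT replicates 2 and 4. An exchange of labels between the MN1 groups is argued against by Hopx, since the highest MN1_KO library held 3.51 CPM and the lowest MN1_WT library 14.1 CPM, and by Mn1, at 22.1 CPM or more in each MN1_KO library. MN1 present but uncounted is argued against by the Hoxa and Meis1 genes, whose median log2 ratio of replicates 2 and 4 to replicate 3 was -4.01 (SD 1.92, 11 of 12 genes lower). A candidate explanation is that these libraries held few or no MN1-overexpressing cells: the same genes had a median log2 ratio to aged wild type of -0.139 (SD 0.597), against 3.51 for replicate 3. Whether such cells were never there or were lost was not tested.

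B cell genes were lower in the aged knockout (22 of 23 by edgeR; camera adjusted p = 1.49e-36 for the list, adjusted p = 0.221 with an estimated correlation). A larger neutrophil share that thins all other cells alike is argued against, because 0 of the 8 other blood cell type medians (-1.92 to -0.185) lay within the spread of the B cell genes, and 21 of 23 B cell genes lay below -1.92. Fewer B cells and less RNA per B cell cannot be told apart: the SD over the B cell genes was 1.4 against a median SE of 0.498, and both readings allow such a spread. The knockout itself is the biological difference in the design, and it was not separated from differences between the animals.

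Hopx was counted in the MN1 knockout libraries. Reads from the knockout allele itself are argued against if both experiments used 1 allele, which the labels do not state, since the aged knockout held 2 Hopx counts where 209 would be needed. Cells of a single sex in each MN1_KO library are argued against by Y-linked genes at 8.05 CPM or more, against at most 0.152 CPM in the aged libraries and 235 CPM in MN1_WT replicates 2 and 4. Wild-type cells mixed in may contribute, and they cannot be told apart from other sources here: observed Hopx was 2.18, 1.43 and 3.18 times what the Y-linked share predicts for replicates 5, 7 and 8, and Hopx per wild-type cell is not known. No biological explanation was tested.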

How the results depend on the processing

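Leaving out MN1_WT replicates 2 and 4 together was chosen after the data were seen; it leaves 1 MN1_WT library, assumed to vary like the other groups. The other alternatives were planned, and a covariate for sex was not run, since the labels give none and the MN1 libraries hold mixed signals. Unless a cause is given, the cause was not tested.

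In the aged comparison, 4008 genes became 818 with all 12 libraries in the fit, whose shared dispersion includes the more variable MN1 libraries, and 2402 to 4599 with 1 library left out. The call of each of the 143 named genes held with limma-trend and without haemoglobin genes, and of 140 with DESeq2, where 3 more passed. With all 12 libraries in the fit 73 of the calls were lost. Over the runs with 1 library left out 84 calls were lost and 768 stayed the same. Here and for the difference of the knockout effects, the named genes include some that did not pass, such as Cxcl12 and Cxcr4. Such a gene counts as the same while it does not pass, so the share of passing calls that were lost is larger. With an estimated correlation 0 of 22 lists passed.

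In the MN1 comparison, 0 genes passed by edgeR against 1353 at an unadjusted p under 0.05, 565 with DESeq2, 6 with limma-trend and 464 with all 12 libraries in the fit, and 0 to 896 with 1 library left out. Of 22 lists, 0 passed with an estimated correlation and 0 with fry. Without MN1_WT replicates 2 and 4, 13 lists passed, of which HSC stemness, glycolysis and primary granule genes were not among the 22. In that last setting camera's direction turned for 8 lists, with medians of -0.58 (HSC stemness), 0.10 (mitotic), 0.19 (DNA replication), 0.36 (glycolysis), 0.39 (immediate early), -0.33 (Hoxa and Meis1), 0.49 (primary granule) and 0.54 (secondary granule). Of these, HSC stemness, glycolysis, Hoxa and primary granule genes passed in the turned direction (camera adjusted p = 3.4e-05, 0.0082, 0.018 and 0.0018). With 1 library left out, medians ran from -0.165 to 0.179 for oxidative phosphorylation, which passed downward without MN1_KO replicate 8. Those of mature neutrophil genes ran from -1.07 to -0.0793, and without MN1_KO replicate 5 camera turned upward and the list passed (camera adjusted p = 0.048).

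For the difference of the knockout effects, 463 genes became 1671 with DESeq2, 40 without MN1_WT replicates 2 and 4, and 53 to 3337 with 1 library left out. Of the 124 named genes, 41 calls were lost without MN1_WT replicates 2 and 4, and 308 over the runs with 1 library left out, where 1124 stayed the same. Of 16 lists, 0 passed with an estimated correlation and 4 lists passed fry. Without MN1_WT replicates 2 and 4 camera's direction turned for HSC stemness (0.038), Hoxa and Meis1 (0.31) and monocyte and macrophage genes (0.88).

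For MN1_WT against aged_WT, 499 genes became 1791 with DESeq2, 329 with the stricter filter, which tests fewer genes, 2465 without MN1_WT replicates 2 and 4, and 78 to 397 with 1 library left out. Of 20 lists, 1 passed with an estimated correlation, and 10 lists passed fry. Camera's direction turned without replicates 2 and 4 for HSC stemness (1.15) and cholesterol synthesis genes (0.019). The mitotic median ran from -0.20 to 0.20, and without MN1_WT replicate 3 that list passed upward (camera adjusted p = 0.0054).

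For MN1_KO against aged_KO, 5281 genes became 2515 to 7366 with 1 library left out, and with an estimated correlation 0 of 24 lists passed. At an unadjusted threshold 432 genes were shared in direction between the knockout effects, against 0 at the adjusted one. Depth of 16544407 to 28409046 counts leaves genes with 1 to 3 counts in a group with wide intervals, as for Hopx.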

Other observations

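The counts of other splits below were planned; the levels of single genes were looked up after the data were seen. Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The aged comparison gave 4008 genes and at most 0 in another split, with 1 of 10 splits as large. MN1_WT against aged_WT gave 499 and 0 (1 of 10), and MN1_KO against aged_KO gave 5281 and 0 (1 of 10). The MN1 comparison gave 0 genes by edgeR (1353 at an unadjusted p under 0.05, 565 with DESeq2, 6 with limma-trend). With a count of 0, 10 of 10 splits gave as many by construction, so this share cannot decide about chance. The highest other split of the MN1 comparison gave 2826 genes, with MN1_WT replicates 2 and 4 and MN1_KO replicate 8 against the rest. That count points to a structure of the samples.

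The levels of 4 single genes are given as values, with no test. Cd34 stood at 57.9 and 20.2 CPM in MN1_WT replicates 2 and 4 and at 754 CPM in replicate 3, and at 748, 555 and 109 CPM in MN1_KO replicates 5, 7 and 8. Flt3 stood at 14.1 and 4.48 CPM against 715 CPM, and at 523, 377 and 94.4 CPM. Sox21 did not set MN1_KO replicate 8 apart: it stood at 0.158 and 0.12 CPM against 85.4 CPM, and at 36.3, 44.6 and 44.4 CPM. Stfa1, a neutrophil stefin gene with close paralogs, stood at 801, 1980 and 5570 CPM in MN1_KO and at 22.3 CPM or less in MN1_WT.

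Liver genes were higher in the aged than in the MN1 libraries. Alb stood at 19.8 to 38.3 CPM and Ttr at 1.16 to 3.44 CPM, against 0 CPM of both in each MN1 library. Apoa2, Hpx and Fgb were lower but not absent in the MN1 libraries, with at most 0.329, 0.192 and 0.131 CPM. In the aged libraries they stood at 0.774 to 1.72, 1.65 to 4.89 and 1.16 to 3.28 CPM. The source was not tested.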
